A study of Mus musculus with 24 samples.

How the data were processed

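The series holds 12 RNA-seq and 12 ATAC-seq libraries of mouse CD8 T cells in 4 groups of 3 per assay. RNA-seq libraries were made by poly(A) capture, and the deposited values are estimated counts per gene from RSEM; per the submitters' processing notes RSEM 1.2.12 and Bowtie2 2.2.0 were used. For ATAC-seq the deposited values are read counts in 75802 peaks of mm10, after removal of duplicates and mitochondrial reads per the file headers; the notes also name Trimmomatic, BWA, Picard, MACS2, bedtools and edgeR 3.20.9. The deposited RNA values were checked for earlier adjustment: 99.24% of the non-zero values were whole within 1e-09, and of 460 genes with a value above 1 that was not whole, 448 had counts of 0 throughout 1 replicate number. Of 5775 ways to part the 12 libraries into 3 sets of 4, the parting by replicate number ranked 1 by this count; the next best had 425 such genes and the mean was 386.3. The estimated counts thus appear to have been adjusted for replicate number by the authors, which would make the spread within groups too small in the RNA-seq tests.

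Counts were rounded, genes or peaks with low counts were removed with filterByExpr, libraries were scaled by TMM, and 1 quasi-likelihood model per assay was fitted to all 12 libraries with edgeR 4.0.16 (residual degrees of freedom 8, no replicate term). The model gave 5 comparisons per assay: each treatment against NaCl, lactate with Oxyrase against lactate, and pyruvate against lactate. P-values were adjusted by Benjamini and Hochberg over all tested features of a comparison, with 0.05 as threshold; the SE is the log2 fold change divided by the square root of F. The filter left 14749 of 55401 genes and removed no peak. The biological coefficient of variation was 5.05% in RNA and 9.70% in ATAC. Principal components used log2 CPM with a prior count of 2. Gene symbols came from the reference table, which matched 55141 of 55401 identifiers. Peaks were placed with GRCm38.p6 gene coordinates; since strand was not used, a peak counted as a gene-end peak where it lay within 1 kb of either annotated end (2.5 kb and 10 kb as alternatives). Peaks did not overlap and had a median width of 438 bp (116 to 4225 bp).

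Gene lists for metabolism, stress, T cell function, division, chromatin enzymes and the markers of other cells were written before the data were examined, as were the comparisons, the alternatives and the rule for naming genes, except where the closing section says otherwise. In each comparison 31 lists had enough measured members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation and fry as alternatives, and with members adjusted over the list alone. Named genes were the 6 highest and 6 lowest log2 fold changes among called genes with a symbol other than a predicted name, a mean log2 CPM of at least 3 whose groups did not overlap, which chance gives in 10% of genes for 3 against 3; up to 4 members with the largest change from each list that was called or had at least 3 called members; and 20 genes fixed in advance. Named peaks were the 4 highest and 4 lowest by the same rule and the called peak of smallest p at each of the 20 genes. Genes beyond the rule are marked as chosen after their values were seen, and the values of some genes within it are not reported here. Equivalence of pyruvate and lactate used the 95% interval of their difference and a margin of 1.5-fold (2-fold as alternative). Shares of counts carry Wilson 95% intervals, and these intervals and the floor of 3 counts cover counting error only. Fisher's exact test compared peak locations, and permutation tests with 100000 draws compared transcripts with peaks. Likeness between comparisons that share libraries was set against 10 simulations with no effect. Simulated fold changes were differences of mean log2 CPM, whereas the observed ones were estimates of the model.

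The pipeline was tested on simulated data for pyruvate against NaCl with 200 changed features. In RNA 60% of genes changed by 1.25-fold were recovered, 70% at 1.5-fold and 88% at 2-fold and at 4-fold, with 10 false calls of 163; in ATAC 15 of 127 calls were false. A simulated list raised by 1.2-fold was called, and 0 of 40 unchanged lists were. The simulated genes varied independently, so this does not test the preset correlation on lists whose genes move together. Alternatives changed the scaling, the filter, the threshold, the samples in the model, the tool (DESeq2 1.42.0) and the libraries, leaving out each in turn, and added replicate number as a term. A trend on mean accessibility (loess span 0.3) and a separate scaling of gene-end peaks were added after the peak counts and locations were seen. A correction for GC content needs a genome sequence and was not run. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.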

Results

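Mouse CD8 T cells (C57BL/6J, spleen and lymph nodes) were activated in culture and, from day 2 to day 3, received 20 mM of sodium chloride (NaCl), sodium pyruvate or lactate, or lactate together with Oxyrase, a bacterial membrane preparation whose enzymes consume the oxygen in a medium. Transcripts were measured by RNA-seq and accessible chromatin by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. Each assay had 12 libraries, 3 per group, so 24 in all. The series title names pyruvate, lactate and hypoxia as the conditions of interest; because Oxyrase was given only with lactate, its effect was read against lactate alone. RNA libraries held 26.04 to 39.64 M counts (M, mega; NaCl 3 lowest, pyruvate 2 highest), and 14749 of 55401 genes were tested. ATAC libraries held 25.31 to 37.07 M counts in 75802 peaks (lactate 2 lowest, pyruvate 1 highest), with a median of 134 to 213 counts per peak. At these depths 3 counts, the most that a count of 0 allows, corresponded to 0.0757 to 0.115 counts per M counts (CPM) in RNA and 0.0809 to 0.119 CPM in ATAC libraries, for counting error only.

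In principal components of the tested features, the Oxyrase libraries of both assays stood apart from the other 9. The leading component held 45.2% of the variance in RNA and 42.2% in ATAC; the next held 10.8% and 14.2%. Among the RNA libraries, the 3 replicates of each group lay together. In ATAC, NaCl 3 lay beside lactate 1 rather than with NaCl 1 and NaCl 2, and the count of peaks for lactate against NaCl is also given without it. Below, levels are CPM as mean ± SD of 3 libraries, and changes are log2 fold changes ± SE with edgeR adjusted p-values. A gene or peak is said to rise or fall only where its adjusted p was under 0.05. Genes or peaks given as highest or lowest in a comparison are so only among those called with a mean log2 CPM of at least 3 whose groups did not overlap. The labels do not say whether the libraries of a group came from separate animals or cultures, so these p-values measure at most the spread between these samples. In RNA that spread appears to have been lowered by an earlier adjustment for replicate number, so the RNA p-values may be too small. With replicate number as a term fewer genes were called in each comparison, and those counts are given in the closing section.

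**Figure D1:**
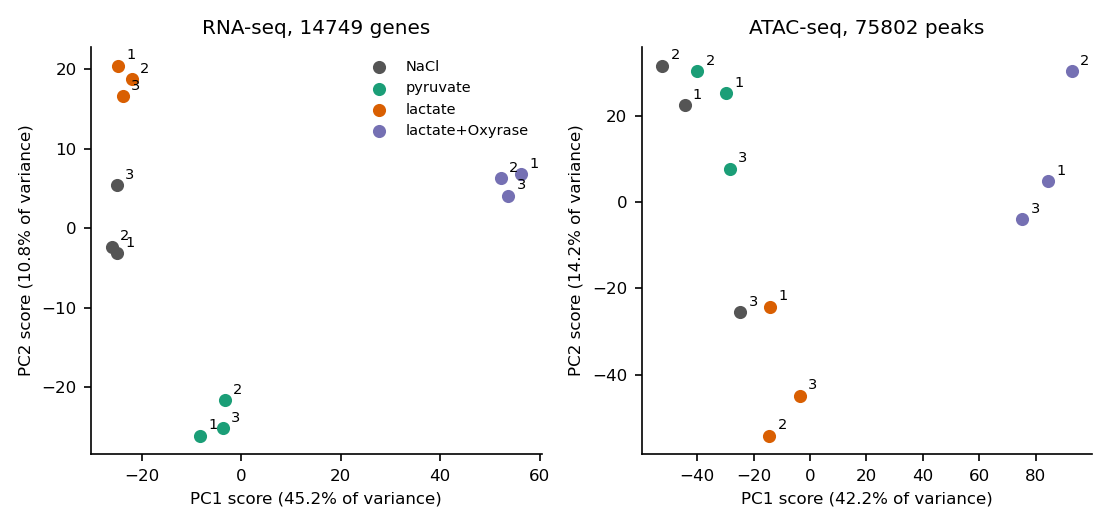
Scores of the 12 RNA-seq (left, 14749 genes) and 12 ATAC-seq libraries (right, 75802 peaks) on the first and second principal components of log2 CPM, colored by treatment and numbered by replicate. Oxyrase libraries separate along the first component (45.2% of the variance in RNA, 42.2% in ATAC), and ATAC library NaCl 3 lies beside lactate 1.

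Pyruvate was compared with NaCl to see what the compound did at equal sodium. Havcr2 (ENSMUSG00000020399), which encodes the inhibitory receptor TIM-3, rose from 1.34 ± 0.598 CPM in NaCl to 18.8 ± 3.53 CPM with pyruvate (SD, n = 3; log2 fold change 3.81 ± 0.20, adjusted p = 3.74e-09). Srxn1 (ENSMUSG00000032802), the sulfiredoxin that repairs oxidized peroxiredoxins, rose 5.40-fold, from 4.34 ± 0.769 to 23.6 ± 4.43 CPM (n = 3, adjusted p = 4.41e-09). Cytotoxic and cytokine genes rose with them: perforin, Prf1 (ENSMUSG00000037202), from 125 ± 14.6 to 282 ± 31.8 CPM (2.25-fold) and interferon gamma, Ifng (ENSMUSG00000055170), from 799 ± 48.1 to 1276 ± 136 CPM (1.60-fold; n = 3 each). Among the genes that fell, Ifi27l2a (ENSMUSG00000079017), an interferon-stimulated gene, went from 21.6 ± 4.23 to 11.1 ± 1.92 CPM, 1.93-fold lower (n = 3), and Oas3 (ENSMUSG00000032661), an interferon-induced RNA sensor, was 1.86-fold lower.

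Across the transcriptome 2313 genes passed the test, 1387 higher and 926 lower with pyruvate. At a mean log2 CPM of at least 3, the other genes with the highest changes encode secreted or surface proteins: Spp1 (ENSMUSG00000029304), osteopontin, at 1.93 ± 0.07; the chemokine Ccl9 (ENSMUSG00000019122) at 1.86 ± 0.15; the fatty acid scavenger receptor Cd36 (ENSMUSG00000002944) at 1.83 ± 0.10; and galectin-3, Lgals3 (ENSMUSG00000050335), at 1.79 ± 0.08. The lowest also held Bmyc (ENSMUSG00000049086) (-0.73 ± 0.09), the adaptor Sh2d1a (ENSMUSG00000005696) (-0.67 ± 0.07), the semaphorin receptor Plxnc1 (ENSMUSG00000074785) (-0.64 ± 0.05) and mt-Nd4l (ENSMUSG00000065947), a subunit of respiratory complex I (-0.62 ± 0.14). Of the effector list, 18 of 24 measured members rose and 1 fell (19 and 2 adjusted over the list alone). Its list test gave adjusted p = 1.13e-38, and adjusted p = 0.00766 with an estimated correlation. The members that rose included Prdm1, the terminal differentiation factor Blimp-1 (1.47 ± 0.20), Csf2 (1.44 ± 0.11), the NK-type receptor Klrc1 (1.24 ± 0.04) and granzyme B, Gzmb (0.44 ± 0.07). Tnf rose too (0.27 ± 0.07, adjusted p = 0.0124), but its adjusted p was 0.061 without NaCl 3 and 0.077 without pyruvate 2. In the NRF2 and glutathione list, which covers defence against oxidants, 7 of 21 measured members rose and 0 fell (8 and 1 adjusted over the list alone). Beside Srxn1 these included the quinone reductase Nqo1 (2.33 ± 0.25), the heme oxygenase Hmox1 (0.46 ± 0.11) and the thioredoxin reductase Txnrd1 (0.41 ± 0.04). That list test gave adjusted p = 1.68e-05, and adjusted p = 0.0329 with an estimated correlation.

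Of the HIF target genes that mark a hypoxia response, 14 of 31 measured members rose and 0 fell (19 and 0 adjusted over the list alone). The hypoxia response list as a whole gave adjusted p = 3.23e-09, and adjusted p = 0.166 with an estimated correlation. Anxa2 (0.56 ± 0.05) and the mitophagy receptor Bnip3 (0.51 ± 0.09) were among them, while Vegfa stood at 0.27 ± 0.09 (adjusted p = 0.0503). Glycolytic enzymes moved by small steps: 6 of 16 measured members rose and 0 fell (7 and 1 adjusted over the list alone), among them pyruvate kinase, Pkm (0.30 ± 0.04), aldolase, Aldoa (0.27 ± 0.04), and hexokinase, Hk1 (0.27 ± 0.05), with adjusted p = 0.000189, and adjusted p = 0.344 with an estimated correlation. Lactate dehydrogenase, Ldha, stood at 0.08 ± 0.04 (adjusted p = 0.205) and the monocarboxylate transporters at -0.01 ± 0.04 for Slc16a1 (adjusted p = 0.947) and 0.39 ± 0.08 for Slc16a3, which rose. Of the activation list, 10 of 25 measured members rose and 2 fell (14 and 2 adjusted over the list alone). The T cell activation list as a whole gave adjusted p = 1.68e-05, and adjusted p = 0.12 with an estimated correlation. Egr2 (0.57 ± 0.08) and Cd44 (0.47 ± 0.05) rose. Among inhibitory receptors and exhaustion factors, 8 of 20 measured members rose and 4 fell (9 and 4 adjusted over the list alone). The inhibitory receptors and exhaustion factors list as a whole gave adjusted p = 0.000256, and adjusted p = 0.12 with an estimated correlation. Beside Havcr2, Eomes (0.38 ± 0.08) and the PD-1 ligand Cd274 (0.33 ± 0.05) rose, whereas PD-1 itself, Pdcd1, stood at -0.01 ± 0.04 (adjusted p = 0.952) and Tox at 0.17 ± 0.08 (adjusted p = 0.162). Of the fatty acid synthesis genes 1 of 16 measured members rose and 6 fell (1 and 8 adjusted over the list alone), with adjusted p = 0.00467, and adjusted p = 0.216 with an estimated correlation, led by the elongase Elovl6 (-0.60 ± 0.07) and the desaturase Fads2 (-0.48 ± 0.10). In the nuclear-encoded respiratory chain 0 of 34 measured members rose and 6 fell (0 and 7 adjusted over the list alone). The nuclear-encoded respiratory chain list as a whole gave adjusted p = 0.000532, and adjusted p = 0.332 with an estimated correlation. Cyc1 (-0.23 ± 0.05) was 1 of them.

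Interferon-stimulated genes divided under pyruvate: 5 of 29 measured members rose and 14 fell (5 and 15 adjusted over the list alone). The interferon-stimulated genes list as a whole gave adjusted p = 0.00204, and adjusted p = 0.484 with an estimated correlation. Usp18, which removes the ubiquitin-like modifier ISG15 from proteins, fell with them (-1.63 ± 0.28). For DNA replication 1 of 30 measured members rose and 6 fell (2 and 8 adjusted over the list alone). The DNA replication list as a whole gave adjusted p = 0.00467, and adjusted p = 0.118 with an estimated correlation. Dut (-0.26 ± 0.04) and Cdt1 (-0.25 ± 0.05) fell. The proliferation marker Mki67 stood at 0.00 ± 0.06 (adjusted p = 0.971) and Myc at 0.02 ± 0.04 (adjusted p = 0.838). Markers of other cells and of the lineage itself moved beside these groups. Of the CD8 T lineage list, 0 of 12 measured members rose and 7 fell (1 and 9 adjusted over the list alone). The CD8 T lineage list as a whole gave adjusted p = 0.000169, and adjusted p = 0.118 with an estimated correlation. Cd2 (-0.40 ± 0.06) and Cd8b1 (-0.25 ± 0.04) fell. For the NK list 2 of 3 measured members rose and 0 fell (2 and 0 adjusted over the list alone), with adjusted p = 0.00023, and adjusted p = 0.044 with an estimated correlation, among them Klri2 (1.26 ± 0.09), and for the B cell list 0 of 8 measured members rose and 2 fell (0 and 2 adjusted over the list alone), with adjusted p = 0.0426, and adjusted p = 0.168 with an estimated correlation, among them Ighm (-0.47 ± 0.04). Myeloid and dendritic markers were low, and 3 of 9 measured members rose and 0 fell (3 and 1 adjusted over the list alone). The myeloid and dendritic list as a whole gave adjusted p = 0.145, and adjusted p = 0.312 with an estimated correlation. Other lists called, each with the measured members that rose and fell, then those adjusted over the list alone, were TCA cycle (0 and 4 of 18; 0 and 4), mitochondrially encoded mRNAs (0 and 2 of 13; 0 and 2), cholesterol synthesis (0 and 6 of 24; 0 and 6), cell cycle arrest and p53 targets (6 and 0 of 19; 6 and 0), ribosome biogenesis and MYC targets (0 and 2 of 27; 0 and 2) and osmotic stress (3 and 1 of 11; 4 and 1). Their list tests gave adjusted p = 0.0125 to 0.0437, and 0.312 to 0.496 with an estimated correlation. Only the effector, NRF2 and NK lists kept their call here with an estimated correlation. Without pyruvate 2 the count of genes called was 1281, and without NaCl 2 it was 1491.

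**Figure D2:**
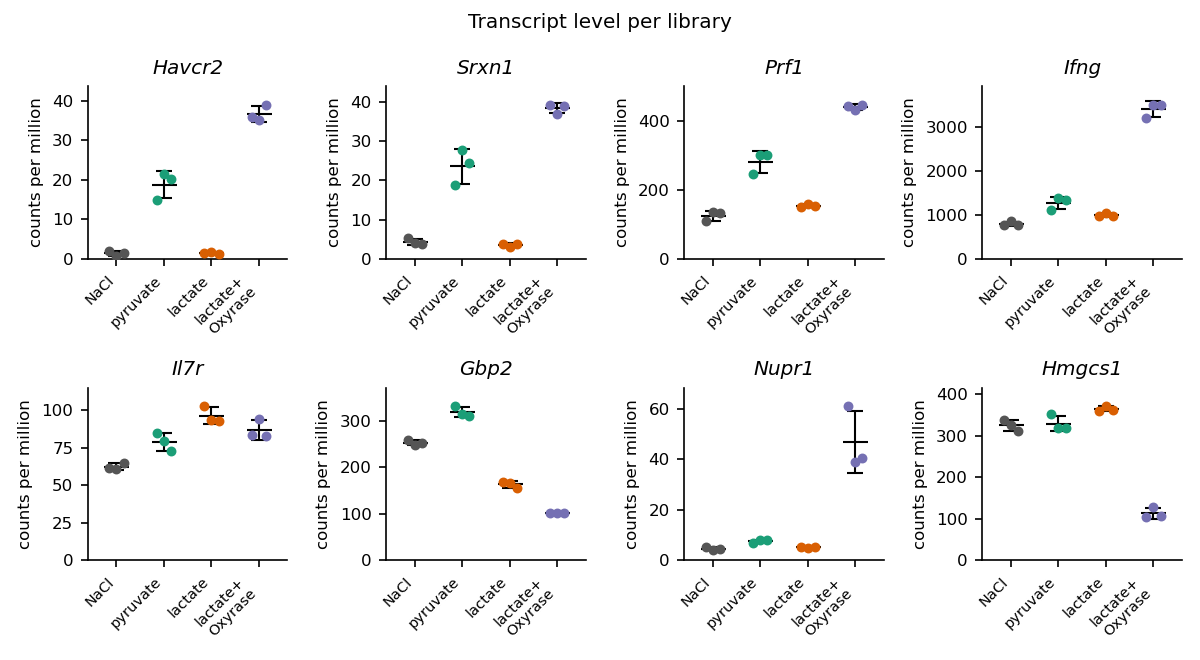
Level in CPM of 8 transcripts in each of the 12 RNA-seq libraries by treatment; points are libraries, the black mark is the mean and the bar the SD of 3 libraries. Havcr2 averaged 1.34 CPM in NaCl, 18.8 with pyruvate, 1.47 with lactate and 36.7 with lactate and Oxyrase.

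In chromatin, no peak was called between pyruvate and NaCl without a replicate term in the model, and 1 was called with it. edgeR called 0 of 75802 peaks (lowest adjusted p = 0.172), with 4060 at an unadjusted p under 0.05, and DESeq2 called 0. In data simulated for this comparison, 46% of peaks given a 1.5-fold change were recovered, 72% at 2-fold and 100% at 4-fold. At the smallest change simulated, 6% of peaks were recovered, against 60% of genes in RNA. Smaller changes were thus often missed in the simulation, and more often in peaks than in transcripts. The same model did call 4857 peaks for lactate against NaCl, of which 38 had an absolute log2 fold change of at least 1.

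Lactate was compared with NaCl in the same way, and fewer transcripts were called than for pyruvate. Il7r (ENSMUSG00000003882), the interleukin-7 receptor of naive and memory T cells, rose from 62.4 ± 2.17 CPM in NaCl to 96.5 ± 5.67 CPM with lactate (SD, n = 3), 1.54-fold (log2 fold change 0.63 ± 0.06, adjusted p = 1.19e-05). Gbp2 (ENSMUSG00000028270), an interferon-induced guanylate-binding protein, fell from 253 ± 5.19 to 163 ± 7.72 CPM, 1.55-fold lower (n = 3, adjusted p = 1.4e-07), and the immunity-related GTPase Iigp1 (ENSMUSG00000054072) was 1.78-fold lower (87.9 ± 8.73 to 49.2 ± 2.08 CPM, n = 3). Zbtb7b (ENSMUSG00000028042), the CD4 lineage factor ThPOK, rose 1.61-fold, from 9.97 ± 1.03 to 16.0 ± 0.455 CPM (n = 3). Both mitochondrial ribosomal RNAs rose, mt-Rnr2 (ENSMUSG00000064339) by 0.66 ± 0.08 and mt-Rnr1 (ENSMUSG00000064337) by 0.64 ± 0.12 (log2); the libraries were made from poly(A) RNA, so these transcripts are read with that limit.

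In all, 1140 genes passed the test, 532 higher and 608 lower. With no filter on low counts there were 1760, 939 higher and 821 lower. With replicate number as a term there were 671, 288 higher and 383 lower. The highest and lowest also held the calcium pump Atp2b4 (ENSMUSG00000026463) (0.68 ± 0.10), the transporter gene Slc35d3 (ENSMUSG00000050473) (0.60 ± 0.10), Ptprn (ENSMUSG00000026204) (-0.98 ± 0.16), Idi2 (ENSMUSG00000033520) (-0.91 ± 0.16) and proenkephalin, Penk (ENSMUSG00000045573) (-0.88 ± 0.09). Of the p53 targets 0 of 19 measured members rose and 7 fell (0 and 12 adjusted over the list alone). The cell cycle arrest and p53 targets list as a whole gave adjusted p = 6.59e-07, and adjusted p = 0.418 with an estimated correlation. Examples were Phlda3 (-0.62 ± 0.12), the death-promoting Bbc3 (-0.49 ± 0.09) and Bax (-0.33 ± 0.06), and the cyclin-dependent kinase inhibitor Cdkn1a (-0.28 ± 0.05). Among interferon-stimulated genes 0 of 29 measured members rose and 6 fell (0 and 8 adjusted over the list alone). The interferon-stimulated genes list as a whole gave adjusted p = 3.37e-09, and adjusted p = 0.652 with an estimated correlation. Gbp5 (-0.47 ± 0.04) and the factor Irf1 (-0.36 ± 0.04) fell beside Gbp2. For ribosome biogenesis and MYC targets 3 of 27 measured members rose and 0 fell (6 and 0 adjusted over the list alone), with adjusted p = 0.00365, and adjusted p = 0.652 with an estimated correlation, among them nucleolin, Ncl (0.28 ± 0.06). Of ATF4 targets, which mark the integrated stress response, 3 of 35 measured members rose and 1 fell (8 and 1 adjusted over the list alone). The integrated stress response list as a whole gave adjusted p = 0.00343, and adjusted p = 0.652 with an estimated correlation. The CD8 T lineage list moved beside these: 0 of 12 measured members rose and 2 fell (1 and 5 adjusted over the list alone). The CD8 T lineage list as a whole gave adjusted p = 0.0315, and adjusted p = 0.652 with an estimated correlation. Cd5 fell (-0.24 ± 0.04).

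The effector list was not called against NaCl (5 of 24 measured members rose and 2 fell, 6 and 4 adjusted over the list alone; list test adjusted p = 0.336), although Gzmb (0.38 ± 0.07), Ifng (0.32 ± 0.06) and the activating receptor Klrk1 (0.32 ± 0.06) rose. In the T cell activation list 0 of 25 measured members rose and 3 fell (1 and 6 adjusted over the list alone), with adjusted p = 0.0126, and adjusted p = 0.652 with an estimated correlation. Other lists called, each with the measured members that rose and fell, then those adjusted over the list alone, were glycolytic enzymes (3 and 0 of 16; 4 and 1), mitosis (2 and 0 of 26; 2 and 1) and osmotic stress (0 and 3 of 11; 0 and 3). Their list tests gave adjusted p = 0.00343 to 0.0295, and 0.418 to 0.652 with an estimated correlation. Havcr2 stood at 0.13 ± 0.30 (adjusted p = 0.84), Tnf at 0.08 ± 0.07 (adjusted p = 0.546) and Ldha at 0.05 ± 0.04 (adjusted p = 0.503). Among the HIF targets 1 of 31 measured members rose and 3 fell (3 and 4 adjusted over the list alone) and the list was not called (adjusted p = 0.501; median -0.01, mean 0.03 and test direction down, so median and mean differ in sign); the histone demethylase Kdm3a fell (-0.35 ± 0.05). None of the 9 lists called for lactate against NaCl kept its call with an estimated correlation. The count of genes rested on single libraries: it was 530 without NaCl 1, 450 without NaCl 2, 517 without lactate 2 and 670 without lactate 3.

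With 1 scaling for all peaks, the chromatin that closed with lactate lay mostly at gene ends. Of 75802 peaks, 4857 passed the test, 856 more and 4001 less accessible than in NaCl. A peak at chromosome 1, 86342251 to 86343441 (mm10), 1278 bp from Ncl, opened from 10.96 ± 1.90 to 18.8 ± 1.82 CPM (SD, n = 3; log2 fold change 0.77 ± 0.14, adjusted p = 0.000604). Another within Slc38a11, at chromosome 2, 65342093 to 65342554, opened by 0.59 ± 0.11. A peak in the gene of tumor necrosis factor, Tnf, at chromosome 17, 35201906 to 35202364, closed from 28.9 ± 5.59 to 19.3 ± 3.42 CPM (n = 3; -0.58 ± 0.11, adjusted p = 0.000811), and so did peaks 19596 bp from Sik1 (chromosome 17, 31875400 to 31875732; -0.86 ± 0.14), 10478 bp from Ankrd6 (chromosome 4, 32961363 to 32961984; -0.85 ± 0.14), 10862 bp from Tspan3 (chromosome 9, 56171932 to 56172440; -0.83 ± 0.14) and 38191 bp from Csf2 (chromosome 11, 54208550 to 54209079; -0.83 ± 0.13). Of the 4001 closed peaks, 2559 (64.0%) lay within 1 kb of an annotated gene end, against 17.4% of peaks not called (odds ratio 8.45; Fisher's exact test, two-sided, p below machine precision). Of the 856 opened peaks 65 (7.59%) did (odds ratio 0.391, p = 1.93e-16 by Fisher's exact test). Peaks are not independent replicates, so the Fisher p-values here and below do not measure the spread between libraries. Of the closed peaks 3740, and of the opened peaks 633, lay above the median of mean log2 CPM. Peaks not called were not matched for level, so the odds ratios may partly reflect which peaks are easier to call. Over all peaks the median log2 fold change was -0.11 at gene ends and 0.06 elsewhere; it was -0.03 and 0.13 with library size alone, and 0.02 and 0.01 where both classes were scaled apart, which removes the difference by construction. In that scaling 36.4% of 3118 closed and 58.5% of 843 opened peaks lay at gene ends.

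Counts in the 14943 gene-end peaks made up 46.4% ± 1.86 of an NaCl library, 46.5% ± 1.07 with pyruvate, 43.7% ± 0.78 with lactate and 41.3% ± 0.75 with lactate and Oxyrase (SD, n = 3). The count of peaks called between lactate and NaCl depended on single libraries: 1262 without NaCl 1, 684 without NaCl 2, 11317 without NaCl 3 (3680 opened and 7637 closed), 2279 without lactate 2 and 1147 without lactate 3. Scaling by library size alone put the median log2 fold change of all peaks at 0.10, against 0.03 by TMM, and gave 2303 opened and 2764 closed peaks, and a per-library trend on mean accessibility gave 1885 and 3628.

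**Figure D3:**
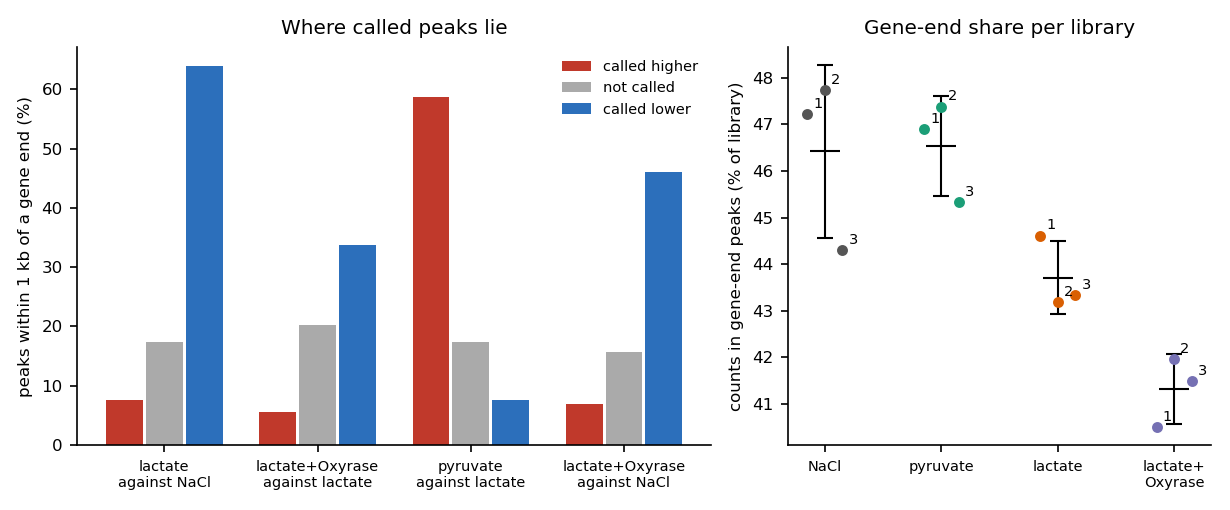
Left, share in percent of ATAC peaks called higher, not called or called lower that lie within 1 kb of an annotated gene end, for 4 comparisons; right, share of each library's counts in gene-end peaks (axis not from 0; numbered points are libraries, bars mean ± SD, n = 3). Peaks closed by lactate lay at gene ends in 64.0% of cases against 17.4% of peaks not called, and the share of counts there averaged 46.4% in NaCl and 41.3% with lactate and Oxyrase.

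Oxyrase together with lactate was compared with lactate alone, since both groups were given lactate. The comparison adds the whole Oxyrase preparation, so loss of oxygen is not separated from other effects of it, such as a change in the lactate left in the medium; levels of oxygen and lactate were not analysed here. Inhba (ENSMUSG00000041324), a subunit of activin, rose from 3.69 ± 0.694 to 120.4 ± 10.3 CPM (SD, n = 3), 32.1-fold (log2 fold change 5.01 ± 0.15, adjusted p = 1.22e-13), and Il23a (ENSMUSG00000025383), a subunit of interleukin-23, rose 31.6-fold, from 10.4 ± 0.869 to 326 ± 53.9 CPM (n = 3). Havcr2 rose 24.98-fold, to 36.7 ± 2.07 CPM (n = 3), and Ifng 3.41-fold, from 1001 ± 45.2 to 3409.9 ± 179.9 CPM (n = 3). The fatty acid elongase Elovl6 (ENSMUSG00000041220) fell from 78.9 ± 4.54 to 16.2 ± 2.39 CPM, 4.87-fold lower (n = 3, adjusted p = 5.39e-13). Each of the 35 measured ATF4 targets rose and each of the 24 measured cholesterol synthesis genes fell.

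Of 14749 genes tested, 7323 were called, 3843 higher and 3480 lower with Oxyrase. The highest further included Ptprn (ENSMUSG00000026204) (4.80 ± 0.12), Ccl9 (ENSMUSG00000019122) (4.17 ± 0.14) and interleukin-3, Il3 (ENSMUSG00000018914) (4.08 ± 0.13); the lowest at a mean log2 CPM of at least 3 were Itih5 (ENSMUSG00000025780) (-2.36 ± 0.14), Elovl6, Tnip3 (ENSMUSG00000044162) (-2.21 ± 0.17), Fads2 (ENSMUSG00000024665) (-2.03 ± 0.11), Slamf6 (ENSMUSG00000015314) (-1.79 ± 0.09) and Sntb1 (ENSMUSG00000060429) (-1.77 ± 0.14). In the integrated stress response list 35 of 35 measured members rose and 0 fell (35 and 0 adjusted over the list alone). The integrated stress response list as a whole gave adjusted p = 4.79e-30, and adjusted p = 0.0706 with an estimated correlation. Its largest changes outside genes near the floor were the stress factor Nupr1 (3.17 ± 0.15), Vldlr (2.80 ± 0.16) and the cystine transporter Slc7a11 (2.37 ± 0.18). For cholesterol synthesis 0 of 24 measured members rose and 24 fell (0 and 24 adjusted over the list alone). The cholesterol synthesis list as a whole gave adjusted p = 4.27e-46, and adjusted p = 0.0192 with an estimated correlation. Mvd (-1.77 ± 0.08), Dhcr7 (-1.70 ± 0.07) and Hmgcs1 (-1.69 ± 0.06) fell furthest. Fatty acid synthesis genes moved with them: 2 of 16 measured members rose and 13 fell (2 and 13 adjusted over the list alone). The fatty acid synthesis list as a whole gave adjusted p = 1.56e-11, and adjusted p = 0.0192 with an estimated correlation. Of the NRF2 and glutathione list, 12 of 21 measured members rose and 3 fell (12 and 3 adjusted over the list alone). The NRF2 and glutathione response list as a whole gave adjusted p = 1.79e-05, and adjusted p = 0.0202 with an estimated correlation. Nqo1 (3.47 ± 0.24), Srxn1 (3.45 ± 0.13) and the metallothionein Mt2 (2.44 ± 0.07) rose. Hypoxia response genes rose in most cases: 21 of 31 measured members rose and 3 fell (21 and 3 adjusted over the list alone). The hypoxia response list as a whole gave adjusted p = 3.52e-10, and adjusted p = 0.101 with an estimated correlation. They included adrenomedullin, Adm (2.59 ± 0.24), the collagen prolyl hydroxylase P4ha2 (2.42 ± 0.19), Ero1l (1.52 ± 0.06) and Vegfa (2.18-fold), while Ldha (-0.22 ± 0.04) and Pdk1 (-0.34 ± 0.05), also known HIF targets, fell.

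T cell state genes changed in opposite directions. Of the effector list, 20 of 24 measured members rose and 3 fell (20 and 3 adjusted over the list alone). The effector molecules and factors list as a whole gave adjusted p = 4.95e-18, and adjusted p = 0.0192 with an estimated correlation. Csf2 (3.21 ± 0.11), the chemokine Ccl5 (3.11 ± 0.23), Gzmc (2.34 ± 0.13), Prf1 (1.52 ± 0.08) and Gzmb (0.41 ± 0.07) rose, and Tnf stood at 0.08 ± 0.07 (adjusted p = 0.356). Of the naive and memory list, 1 of 21 measured members rose and 17 fell (1 and 17 adjusted over the list alone). The naive and memory T cell factors list as a whole gave adjusted p = 1.39e-06, and adjusted p = 0.0446 with an estimated correlation. Slamf6 and the factor Tcf7 (-0.22 ± 0.04) fell. Inhibitory receptors went both ways (8 of 20 measured members rose and 7 fell, 8 and 7 adjusted over the list alone; list test adjusted p = 0.825, and adjusted p = 0.908 with an estimated correlation): Havcr2, Cd274 (1.00 ± 0.05) and Lag3 (0.23 ± 0.05) rose, Cd101 (-1.95 ± 0.20) and Tox (-0.46 ± 0.08) fell, and Pdcd1 stood at 0.09 ± 0.04 (adjusted p = 0.105). The Cd274 value was chosen after the values were seen. Genes of the interleukin-2 and STAT5 response fell more often than they rose (2 of 14 measured members rose and 7 fell, 2 and 8 adjusted over the list alone; list test adjusted p = 0.00119, and adjusted p = 0.0695 with an estimated correlation), among them the kinase Pim2 (-1.68 ± 0.05) and Socs2 (-1.06 ± 0.07). Of the DNA replication genes 4 of 30 measured members rose and 19 fell (4 and 19 adjusted over the list alone). The DNA replication list as a whole gave adjusted p = 1.02e-05, and adjusted p = 0.0192 with an estimated correlation. Rrm1 (-0.58 ± 0.04) and Lig1 (-0.52 ± 0.04) fell. In ribosome biogenesis and MYC targets 1 of 27 measured members rose and 17 fell (1 and 18 adjusted over the list alone). The ribosome biogenesis and MYC targets list as a whole gave adjusted p = 1.02e-05, and adjusted p = 0.211 with an estimated correlation. Myc itself fell by 0.69 ± 0.04 on the log2 scale.

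Beside these groups, lineage and other-cell markers moved. Of the CD8 T lineage list 1 of 12 measured members rose and 8 fell (1 and 8 adjusted over the list alone). The CD8 T lineage list as a whole gave adjusted p = 2.66e-06, and adjusted p = 0.0398 with an estimated correlation. Cd8a went from 659 ± 24.1 to 406 ± 7.80 CPM and Cd2 from 225 ± 10.1 to 93.0 ± 4.88 CPM. Myeloid and dendritic markers rose at low levels (6 of 9 measured members rose and 1 fell, 6 and 1 adjusted over the list alone; list test adjusted p = 0.0376, and adjusted p = 0.11 with an estimated correlation), such as Cd68, from 1.52 ± 0.200 to 4.97 ± 0.953 CPM. For the B cell list 2 of 8 measured members rose and 3 fell (2 and 3 adjusted over the list alone), with adjusted p = 0.0157, and adjusted p = 0.0787 with an estimated correlation, and Ighm went from 189.5 ± 3.81 to 69.1 ± 5.19 CPM. For the NK list 2 of 3 measured members rose and 0 fell (2 and 0 adjusted over the list alone), with adjusted p = 0.0385, and adjusted p = 0.16 with an estimated correlation, and Klri2 rose (1.84 ± 0.09). In the CD4 and regulatory T list 2 of 7 measured members rose and 2 fell (2 and 2 adjusted over the list alone) and it was not called (adjusted p = 0.825; median -0.32 and mean -0.09 against a test direction of up): Foxp3 fell (-2.23 ± 0.21) and Zbtb7b rose (1.43 ± 0.08). With an estimated correlation, 7 of the 19 lists called here kept their call: cholesterol synthesis, fatty acid synthesis, NRF2, effector, naive and memory, DNA replication and CD8 T lineage.

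Other programs also moved with Oxyrase. Of TCA cycle genes 1 of 18 measured members rose and 10 fell (1 and 10 adjusted over the list alone). The TCA cycle list as a whole gave adjusted p = 0.00972, and adjusted p = 0.211 with an estimated correlation. Suclg2 (-0.57 ± 0.04) and Idh2 (-0.50 ± 0.05) fell. Of glycolytic enzymes 4 of 16 measured members rose and 5 fell (4 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.435); the glucose transporter Slc2a1 stood at 0.35 ± 0.06 and the monocarboxylate transporter Slc16a1 at -0.19 ± 0.04, both past the test. Among interferon-stimulated genes 2 of 29 measured members rose and 16 fell (2 and 17 adjusted over the list alone). The interferon-stimulated genes list as a whole gave adjusted p = 0.00381, and adjusted p = 0.531 with an estimated correlation. Ifit1 (-2.37 ± 0.29) and Usp18 (-1.84 ± 0.31) fell. Heat shock and unfolded protein genes fell more often than they rose (3 of 23 measured members rose and 11 fell, 3 and 11 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.357 with an estimated correlation), among them the chaperones Hspa8 (-1.03 ± 0.04) and Hsph1 (-0.63 ± 0.03). Of the chromatin dioxygenases, enzymes that need oxygen to demethylate histones or DNA, 11 of 20 measured members rose and 3 fell (11 and 3 adjusted over the list alone). The oxygen-dependent chromatin dioxygenases list as a whole gave adjusted p = 0.0157, and adjusted p = 0.357 with an estimated correlation. Kdm6b (0.88 ± 0.07), Kdm4a (0.85 ± 0.05), Kdm5b (0.57 ± 0.05) and Kdm3a (0.52 ± 0.05) passed the test. In the list of cell cycle arrest and p53 targets 10 of 19 measured members rose and 4 fell (10 and 4 adjusted over the list alone), with adjusted p = 0.0385, and adjusted p = 0.484 with an estimated correlation.

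**Figure D4:**
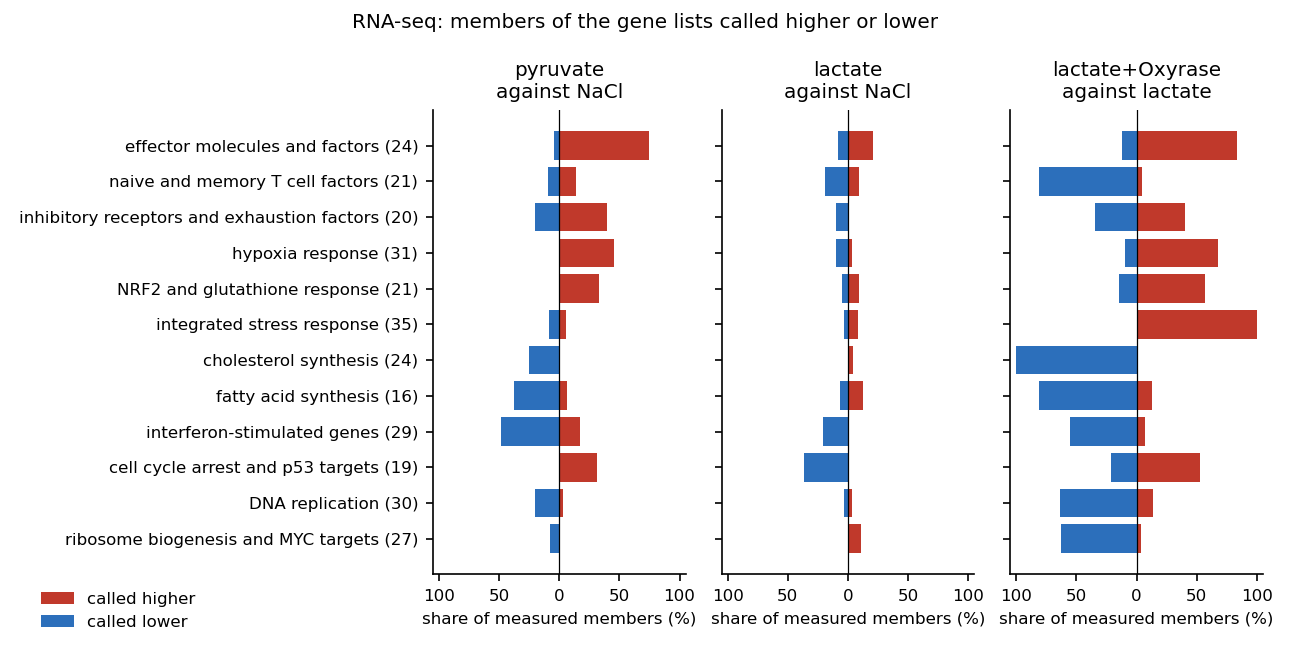
Share in percent of the measured members (number in parentheses) of 12 gene lists that were called higher (red, to the right) or lower (blue, to the left) in 3 RNA-seq comparisons. With Oxyrase against lactate 35 of 35 integrated stress response genes were higher and 24 of 24 cholesterol synthesis genes lower.

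Oxyrase also changed 21539 peaks against lactate, opening 11843 and closing 9696. The peak with the highest change, at chromosome 3, 68608760 to 68609454 (mm10) within Iqschfp and Schip1, opened from 9.29 ± 0.941 to 29.8 ± 3.08 CPM (SD, n = 3; log2 fold change 1.68 ± 0.10, adjusted p = 6.58e-16). Others that opened lay within Mitf (chromosome 6, 97952833 to 97953222; 1.66 ± 0.13) and Clcn3 (chromosome 8, 60954332 to 60955149; 1.59 ± 0.12) and 31760 bp from Csnk1a1 (chromosome 18, 61622080 to 61622571; 1.55 ± 0.12). The peak with the lowest change, 69533 bp from Lonrf2 (chromosome 1, 38723231 to 38724136), closed from 16.8 ± 1.27 to 5.67 ± 0.699 CPM (-1.56 ± 0.11), and another closed within Cenpp and Ecm2 (chromosome 13, 49513412 to 49514234; -1.31 ± 0.14). At genes fixed for display, a peak in Havcr2 (chromosome 11, 46454612 to 46455092) opened by 0.48 ± 0.10 and one in Pdcd1 (chromosome 1, 94047892 to 94048512) by 0.63 ± 0.10, while a peak 30682 bp from Tcf7 (chromosome 11, 52314065 to 52314747; -0.80 ± 0.11) closed. Direction there need not follow the transcript: the called peak of smallest p near Ifng, 15390 bp away (chromosome 10, 118461284 to 118461707), closed by 0.78 ± 0.12 although Ifng RNA rose. Another peak, 24506 bp from Ifng (chromosome 10, 118470400 to 118471011), stood at 25.9 ± 1.6 CPM in lactate and 32.8 ± 1.22 CPM with Oxyrase. It opened by 0.65 ± 0.09 in lactate with Oxyrase against NaCl. Gene ends held 33.7% of closed, 5.55% of opened and 20.3% of uncalled peaks (closed against uncalled, odds ratio 1.99, p = 2.04e-172 by Fisher's exact test). With gene-end and other peaks scaled apart these shares were 15.7%, 13.4% and 21.7%.

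Pyruvate and lactate were compared directly at the same concentration; lactate is pyruvate with its keto group reduced to a hydroxyl group. Havcr2 was 12.8-fold higher with pyruvate (18.8 ± 3.53 against 1.47 ± 0.317 CPM; SD, n = 3; log2 fold change 3.68 ± 0.19, adjusted p = 1.58e-09). Srxn1 was 6.71-fold higher (23.6 ± 4.43 against 3.52 ± 0.436 CPM, n = 3), Ptprn 6.21-fold and the chemokine Ccl1 (ENSMUSG00000020702) 4.75-fold higher. Interleukin-2, Il2 (ENSMUSG00000027720), was 2.12-fold higher (12.8 ± 1.40 against 6.00 ± 0.876 CPM, n = 3) and Gbp2 was higher by 0.97 ± 0.04. Higher with lactate were Elovl6 (-0.86 ± 0.07), the desaturase Scd1 (ENSMUSG00000037071) (-0.74 ± 0.11), mt-Rnr2 (-0.74 ± 0.08), Ifi27l2a (-0.74 ± 0.13), Mfsd13a (ENSMUSG00000025227) (-0.74 ± 0.10) and the mitochondrial carrier Slc25a23 (ENSMUSG00000046329) (-0.74 ± 0.09).

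This comparison called 3534 genes, 1922 higher with pyruvate and 1612 higher with lactate. In the effector list 19 of 24 measured members rose and 1 fell (19 and 2 adjusted over the list alone) with pyruvate, with adjusted p = 1.21e-23, and adjusted p = 0.0368 with an estimated correlation; it was the only list of the 31 tested to keep its call here with an estimated correlation. Ccl5 (1.74 ± 0.25), Prdm1 (1.42 ± 0.20), Csf2 (1.37 ± 0.11) and Prf1 (0.87 ± 0.07) were higher with pyruvate, and Ifng too (0.35 ± 0.06). Gzmb did not differ by the test (0.06 ± 0.07, adjusted p = 0.569; 95% interval -0.08 to 0.20). Of the p53 targets 14 of 19 measured members rose and 0 fell (15 and 0 adjusted over the list alone). The cell cycle arrest and p53 targets list as a whole gave adjusted p = 2.82e-08, and adjusted p = 0.0966 with an estimated correlation. Cdkn1a (0.53 ± 0.05), Ccng1 (0.53 ± 0.07) and Phlda3 (0.62 ± 0.12) were among them. In the hypoxia response list 17 of 31 measured members rose and 0 fell (19 and 1 adjusted over the list alone). The hypoxia response list as a whole gave adjusted p = 2.41e-08, and adjusted p = 0.202 with an estimated correlation. Adm (1.19 ± 0.25) and Anxa2 (0.55 ± 0.05) were higher. For T cell activation 16 of 25 measured members rose and 2 fell (16 and 3 adjusted over the list alone). The T cell activation list as a whole gave adjusted p = 1.82e-08, and adjusted p = 0.0966 with an estimated correlation. Cd44 was higher (0.65 ± 0.05). Markers of other cells moved too: in the NK list 1 of 3 measured members rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.0185, and adjusted p = 0.163 with an estimated correlation, and of the myeloid and dendritic markers 3 of 9 measured members rose and 0 fell (3 and 0 adjusted over the list alone), with adjusted p = 0.0728, and adjusted p = 0.202 with an estimated correlation. Other lists called, each with the measured members that rose and fell, then those adjusted over the list alone, were inhibitory receptors and exhaustion factors (10 and 2 of 20; 12 and 2), NRF2 and glutathione response (6 and 3 of 21; 7 and 5), oxygen-dependent chromatin dioxygenases (8 and 0 of 20; 9 and 0), cholesterol synthesis (0 and 7 of 24; 0 and 7), fatty acid synthesis (0 and 5 of 16; 0 and 5), nuclear-encoded respiratory chain (0 and 4 of 34; 0 and 4) and mitosis (2 and 10 of 26; 2 and 10). Their list tests gave adjusted p = 2.95e-05 to 0.0333, and 0.0966 to 0.522 with an estimated correlation. Lower with pyruvate were ribosome biogenesis and MYC targets (0 of 27 measured members rose and 13 fell, 1 and 20 adjusted over the list alone; adjusted p = 4.25e-05, and adjusted p = 0.248 with an estimated correlation), ATF4 targets (3 of 35 measured members rose and 12 fell, 3 and 14 adjusted over the list alone; adjusted p = 0.00147, and adjusted p = 0.556 with an estimated correlation) and TCA cycle enzymes (0 of 18 measured members rose and 7 fell, 0 and 7 adjusted over the list alone; adjusted p = 0.00466, and adjusted p = 0.221 with an estimated correlation). Interferon-stimulated genes were not called (7 of 29 measured members rose and 7 fell, 7 and 8 adjusted over the list alone; adjusted p = 0.204), and their median of -0.20 and mean of -0.29 opposed the test's upward direction.

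Of the 3095 genes called against NaCl for either compound, 2032 (65.7%) differed between pyruvate and lactate, 1245 higher with pyruvate and 787 higher with lactate. Another 913 (29.5%) did not differ and had a 95% interval within 1.5-fold, and 150 were neither. Of the 4857 such peaks, each called for lactate, 3994 (82.2%) differed, 576 (11.9%) lay within 1.5-fold and 287 were neither. These genes and peaks were chosen with libraries that the second test uses again, which raises the shares that differ, so they do not measure how often the compounds differ. In all, 8804 peaks differed between the compounds, 5184 more accessible with pyruvate and 3620 with lactate. The Tspan3 and Sik1 peaks named above were more accessible with pyruvate, by 0.95 ± 0.14 and 0.90 ± 0.14, as was a peak in Ehd1 (chromosome 19, 6296581 to 6296854; 11.7 ± 1.84 against 6.24 ± 0.795 CPM, n = 3; 0.91 ± 0.14) and the Tnf peak (0.78 ± 0.11). The Ncl peak (-0.73 ± 0.14) and peaks 17769 bp from Crot (chromosome 5, 9014915 to 9015724; -0.82 ± 0.12) and 2261 bp from Actr3 (chromosome 1, 125389699 to 125390644; -0.73 ± 0.09) were more accessible with lactate. Gene ends held 58.7% of the peaks more accessible with pyruvate, 7.65% of those more accessible with lactate and 17.4% of uncalled peaks (odds ratio 6.77 for the first, p below machine precision). With both classes scaled apart the shares were 35.7%, 37.6% and 17.8%, and with library size alone 4119 peaks were more accessible with pyruvate and 6084 with lactate. The count of peaks was 5284 without pyruvate 1, 4445 without pyruvate 2, 4961 without lactate 2 and 3597 without lactate 3.

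Lactate with Oxyrase against NaCl gives the joint change of both additions. Havcr2 rose 27.4-fold, from 1.34 ± 0.598 to 36.7 ± 2.07 CPM (SD, n = 3; log2 fold change 4.77 ± 0.20, adjusted p = 4.39e-12), Il23a 25.6-fold and Ifng 4.27-fold, to 3409.9 ± 179.9 CPM (n = 3). Iigp1, which encodes an interferon-induced GTPase, fell from 87.9 ± 8.73 to 15.3 ± 2.25 CPM (5.77-fold lower, n = 3), and Ifi47 (ENSMUSG00000078920) from 160.5 ± 3.10 to 33.9 ± 1.41 CPM (4.73-fold lower, n = 3). In all, 7492 genes were called, 3915 higher and 3577 lower. Again the 35 measured ATF4 targets rose and the 24 measured cholesterol synthesis genes fell, with adjusted p = 4.15e-35, and adjusted p = 0.0494 with an estimated correlation for the former and adjusted p = 2.32e-42, and adjusted p = 0.0158 with an estimated correlation for the latter (35 and 24 adjusted over the list alone). Of interferon-stimulated genes 1 of 29 measured members rose and 21 fell (1 and 21 adjusted over the list alone). The interferon-stimulated genes list as a whole gave adjusted p = 4.38e-07, and adjusted p = 0.286 with an estimated correlation. Usp18 fell (-2.34 ± 0.30). In the effector list 19 of 24 measured members rose and 3 fell (20 and 3 adjusted over the list alone), with adjusted p = 3.96e-19, and adjusted p = 0.0158 with an estimated correlation, and of the naive and memory list 2 of 21 measured members rose and 14 fell (2 and 15 adjusted over the list alone). The naive and memory T cell factors list as a whole gave adjusted p = 5.26e-07, and adjusted p = 0.0412 with an estimated correlation. Il7r rose (0.48 ± 0.06) and Tcf7 stood at -0.06 ± 0.04 (adjusted p = 0.22). For DNA replication 0 of 30 measured members rose and 19 fell (0 and 19 adjusted over the list alone), with adjusted p = 3.05e-06, and adjusted p = 0.0158 with an estimated correlation, and for the CD8 T lineage 0 of 12 measured members rose and 9 fell (0 and 9 adjusted over the list alone). The CD8 T lineage list as a whole gave adjusted p = 3.05e-08, and adjusted p = 0.0158 with an estimated correlation. Among markers of other cells, in the B cell list 1 of 8 measured members rose and 3 fell (1 and 3 adjusted over the list alone), with adjusted p = 0.00845, and adjusted p = 0.0516 with an estimated correlation, in the NK list 2 of 3 measured members rose and 0 fell (2 and 0 adjusted over the list alone), with adjusted p = 0.0179, and adjusted p = 0.0975 with an estimated correlation, and of the myeloid and dendritic markers 4 of 9 measured members rose and 1 fell (4 and 1 adjusted over the list alone), with adjusted p = 0.098, and adjusted p = 0.198 with an estimated correlation. Other lists called, each with the measured members that rose and fell, then those adjusted over the list alone, were hypoxia response (21 and 4 of 31; 22 and 4), NRF2 and glutathione response (12 and 3 of 21; 12 and 4), fatty acid synthesis (2 and 13 of 16; 2 and 13), TCA cycle (2 and 11 of 18; 2 and 11), IL-2 and STAT5 response (1 and 8 of 14; 1 and 8), ribosome biogenesis and MYC targets (4 and 17 of 27; 4 and 18) and heat shock and unfolded protein response (3 and 10 of 23; 3 and 10). Their list tests gave adjusted p = 2.84e-10 to 0.0483, and 0.0158 to 0.389 with an estimated correlation. The calls of 9 of the 16 lists held with an estimated correlation; beside those just given with a p under 0.05, they were fatty acid synthesis, NRF2, and the interleukin-2 and STAT5 response.

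In chromatin 30885 of 75802 peaks changed between these groups, 16309 opening and 14576 closing. The Iqschfp and Schip1 peak opened by 1.79 ± 0.10 and the peak near Lonrf2 closed by 1.95 ± 0.11 (log2), from 22.0 ± 3.02 to 5.67 ± 0.699 CPM (n = 3). Further closed peaks lay 1000 bp from Mllt6 (chromosome 11, 97661760 to 97662122; -1.61 ± 0.13), within Bdh1 (chromosome 16, 31424401 to 31424815; -1.53 ± 0.13) and 283548 bp from Myc (chromosome 15, 62273909 to 62274411; -1.41 ± 0.12). The Tnf peak closed by 1.09 ± 0.11 (log2), and the Havcr2 peak opened by 0.59 ± 0.10. Gene ends held 46.1% of closed, 7.0% of opened and 15.8% of uncalled peaks (odds ratio 4.58 for the closed; 24.6%, 24.3% and 16.7% with both classes scaled apart). Library size alone put the median log2 fold change of all peaks at 0.14, against 0.03 by TMM, and gave 21433 opened and 10494 closed peaks.

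The responses to pyruvate and to lactate share their NaCl libraries, so some likeness arises without any effect. Across genes their log2 fold changes correlated with r = 0.534 and rho = 0.260, against r = 0.511 and rho = 0.450 in simulated groups with no effect. The same sign was found in 58.4% of genes (simulated 67%), and the covariance was 0.124 against a simulated 0.0322. Genes are not independent replicates. The simulated fold changes were differences of mean log2 CPM, which treat low counts otherwise than the model does. Real effects can also move r, rho and the share of equal sign away from their values with no effect. These measures thus cannot decide on a likeness beyond the shared libraries. Both compounds raised 136 genes, where independent lists of these sizes would share 50.0, and lowered 98 (38.2), while 124 genes went in opposite directions. Across peaks r was 0.242 (simulated 0.507) and the covariance 0.0117 (simulated 0.0170). The NaCl libraries are too few to be divided between both comparisons, so part of any likeness may come from the shared control. Lactate against NaCl and Oxyrase against lactate share the lactate libraries with opposite sign. Across genes r was -0.191 (simulated -0.490) and the covariance -0.0674 (simulated -0.0318), under the limits of the simulation given above. Across peaks r was -0.0480 (simulated -0.502), and 1646 peaks closed in both (511.8 for independent lists).

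Accessibility and transcript change were set side by side for 9776 genes with a peak within 1 kb of a gene end (permutation tests over genes, two-sided, smallest p possible 1e-05; genes are not independent replicates). With Oxyrase against lactate, Spearman's rho across genes was 0.165 (p = 1e-05), and genes whose peak opened had a median RNA log2 fold change of 0.42, against -0.04 for genes whose peak closed (difference 0.46, p = 1e-05). With Oxyrase against NaCl rho was 0.108 (p = 1e-05) and the difference 0.28 (p = 1e-05). For lactate against NaCl rho was 0.0065 (p = 0.5): 2276 genes had a closed gene-end peak, and their median RNA change was 0.0032 against 0.0059 for uncalled genes. For pyruvate against lactate rho was -0.107 (p = 1e-05) and the difference between medians -0.0355 (p = 0.07), or -0.0565 (p = 0.0003) with peaks within 10 kb. For pyruvate against NaCl rho was 0.0001 (p = 1).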

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

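The per-library trend on mean accessibility and the separate scaling of gene-end peaks were chosen only after the result was seen; the other alternatives were fixed before. The location of called peaks at gene ends turned with the scaling. With gene-end and other peaks scaled apart, the opened peaks of lactate against NaCl went from below to above the share of uncalled peaks (7.59% against 17.36%, then 58.48% against 18.53%), as did those of Oxyrase with lactate against NaCl (24.27% against 16.66%) and the peaks more accessible with lactate than with pyruvate (37.6% against 17.82%), while the closed peaks of Oxyrase against lactate went below it (33.68% against 20.31%, then 15.72% against 21.71%). With the trend on mean accessibility removed, the share also rose above that of uncalled peaks for those opened by lactate against NaCl (22.55% against 17.76%) and those more accessible with lactate than with pyruvate (20.46% against 17.13%). The majority direction turned for pyruvate against lactate in ATAC by library size alone (5184 up and 3620 down, then 4119 and 6084), for Oxyrase with lactate against NaCl by DESeq2 size factors (16309 and 14576, then 15071 and 15751) and by the DESeq2 test (14524 and 15467), and for lactate against NaCl in RNA with no filter (532 and 608, then 939 and 821). With an absolute log2 fold change of at least 1 required, RNA counts in the order pyruvate, lactate and Oxyrase with lactate each against NaCl, Oxyrase against lactate, and pyruvate against lactate were 198, 63, 1249, 1206 and 328 genes, and ATAC counts were 38 for lactate and 2640 for Oxyrase against NaCl, 1924 for Oxyrase against lactate and 79 for pyruvate against lactate; the stricter threshold is the cause by its construction. For lactate against NaCl, 1760 genes were called with no filter on low counts and 671 with replicate number as a term. With that term the other RNA counts were lower too. They were 1719 for pyruvate against NaCl, 6740 for Oxyrase against lactate, 2879 for pyruvate against lactate and 6916 for Oxyrase with lactate against NaCl. The apparent earlier adjustment for replicate number would make the RNA counts without the term too high. The cause was not tested. With that term 1 peak was called for pyruvate against NaCl, where the model without it called 0; for lactate against NaCl 6775 peaks were called, 1516 opened and 5259 closed, where the model without it gave 856 and 4001. The other ATAC counts with it were 23712 for Oxyrase against lactate, 10845 for pyruvate against lactate and 32437 for Oxyrase with lactate against NaCl. The cause was not tested.

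Lists called with an estimated correlation numbered 3 for pyruvate, 0 for lactate and 9 for Oxyrase with lactate against NaCl, 7 for Oxyrase against lactate and 1 for pyruvate against lactate, where the preset correlation gave 19, 9, 16, 19 and 16; fry called 19, 3, 23, 23 and 19 in the same order. The cause was not tested beyond the change of test. The difference of RNA medians between genes with opened and closed peaks for pyruvate against lactate was -0.0565 (permutation p = 0.0003) with peaks within 10 kb, and -0.0355 (permutation p = 0.07) within 1 kb; the cause was not tested. The covariance above simulation of the pyruvate and lactate responses was 0.0262 among genes above the median of mean log2 CPM and 0.0917 over all genes; the cause was not tested.

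Leaving out 1 library at a time, the RNA counts ranged over 1281 to 1921 genes for pyruvate against NaCl, 450 to 1126 for lactate against NaCl, 6546 to 6844 for Oxyrase against lactate, 2552 to 2944 for pyruvate against lactate and 6712 to 7032 for Oxyrase with lactate against NaCl. ATAC counts ranged over 684 to 11317 peaks for lactate against NaCl, 16200 to 19031 for Oxyrase against lactate, 3597 to 8150 for pyruvate against lactate and 25131 to 31281 for Oxyrase with lactate against NaCl; pyruvate against NaCl stayed at 0 by edgeR (3451 to 4943 at an unadjusted p under 0.05). Fewer libraries were at hand in each of these fits; why the count of peaks rose without NaCl 3 was not tested further. List counts ranged over 15 to 18, 8 to 9, 17 to 19, 14 to 18 and 15 to 17 in the same order as the RNA counts. Of named calls, 461 of 585 in RNA and 72 of 89 in ATAC passed under each alternative judged by adjusted p alone. The threshold on log2 fold change was not among these alternatives. In RNA the calls kept were 73 of 116 for pyruvate against NaCl, 29 of 65 for lactate against NaCl and 98 of 127 for pyruvate against lactate. With Oxyrase they were 128 of 137 against lactate and 133 of 140 against NaCl. In ATAC they were 7 of 14 for lactate against NaCl and 13 of 19 for pyruvate against lactate. With Oxyrase in ATAC they were 24 of 28 against lactate and 28 of 28 against NaCl.

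Whether replicate numbers pair the RNA libraries could not be read from the values, since an earlier adjustment for replicate number would lower the correlation of libraries of the same number (median -0.15 after removal of group means; 0 of 12 libraries correlated best with their own number). In ATAC the median was 0.12, 10 of 18 pairs were over 0.1 and 7 of 12 libraries correlated best with their own number, a hint of shared signal in the data. The ATAC library names are numbered through the treatments within each replicate number in turn, but the labels give no shared animal or day. Removing low counts left each peak in place, so that alternative had no effect on ATAC. Correction for GC content was not run, since no genome was used here. In the RNA libraries 3 counts correspond to 0.0757 to 0.115 CPM.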

Other observations

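The test of a mislabelled NaCl 3, the tests of NaCl 3 and of the scaling for the missing pyruvate peaks, the tests on myeloid and dendritic markers, and the test of a shared pyruvate and Oxyrase response were chosen only after the result was seen. Under pyruvate the interferon-stimulated genes that rose were guanylate-binding proteins, GTPases that act on intracellular pathogens: Gbp7 (0.72 ± 0.07), Gbp4 (0.39 ± 0.05), Gbp2 (0.33 ± 0.04), Gbp3 (0.26 ± 0.06) and Gbp5 (0.21 ± 0.04; all chosen after their values were seen). Those that fell included Irf7 (-1.34 ± 0.21, chosen in the same way), a factor of the type I interferon response, beside Usp18 and Oas3. Under lactate the guanylate-binding proteins Gbp2 (-0.63 ± 0.04) and Gbp5 (-0.47 ± 0.04) fell.

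Osmotic stress genes, NFAT5 targets, differed between the compounds: 7 of 11 measured members rose and 0 fell (9 and 0 adjusted over the list alone) with pyruvate against lactate, with adjusted p = 6.67e-05, and adjusted p = 0.0966 with an estimated correlation. Against NaCl, 3 rose and 1 fell with pyruvate and 0 rose and 3 fell with lactate. With Oxyrase against lactate several lists were not called: mitochondrially encoded mRNAs (1 of 13 measured members rose and 1 fell, 1 and 1 adjusted over the list alone; adjusted p = 0.915; median -0.006, mean 0.07, test down), the nuclear-encoded respiratory chain (5 of 34 measured members rose and 10 fell, 5 and 10 adjusted over the list alone; adjusted p = 0.452), pyruvate and lactate transport and conversion (11 of 22 measured members rose and 5 fell, 12 and 6 adjusted over the list alone; adjusted p = 0.825), fatty acid oxidation (9 of 17 measured members rose and 4 fell, 9 and 4 adjusted over the list alone; adjusted p = 0.825), histone acetylation enzymes (9 of 26 measured members rose and 7 fell, 9 and 7 adjusted over the list alone; adjusted p = 0.978), mitosis (7 of 26 measured members rose and 7 fell, 7 and 7 adjusted over the list alone; adjusted p = 0.825; median 0.017, mean -0.003, test down) and stromal markers (2 of 5 measured members rose and 1 fell, 2 and 1 adjusted over the list alone; adjusted p = 0.825).

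With 1 scaling for all peaks lactate closed gene-end peaks, and the ATAC library NaCl 3 lay partway to lactate. On an axis from the pyruvate libraries (0) to the lactate libraries (1), over the 8804 peaks called between them, NaCl 3 lay at 0.632. Since the lactate libraries chose these peaks, each was also left out in turn from the choice of peaks and from the axis. Those left out then lay at 0.652, 0.879 and 0.955, and NaCl 3 on the same axes at 0.555, 0.598 and 0.616. The lowest gap, 0.097, was within the SD of 0.158 of the libraries left out, so a mislabelled lactate culture cannot be told apart from an NaCl culture that lay partway. Over the 8804 peaks, replicate 3 lay highest in each group: 0.632 in NaCl, 0.134 in pyruvate, 1.084 in lactate and 0.95 with Oxyrase. The next highest were 0.147, 0.061, 1.02 and 0.896 in the same order. With the trend on mean accessibility removed, this order held except in pyruvate (0.084, against 0.096 for pyruvate 1). A shift common to replicate number 3 was not tested. With the trend removed, the gap of NaCl 3 to NaCl 1 and NaCl 2 was 0.48 against 0.094 between these, which argues against that trend as the whole cause. Its share of counts in gene-end peaks, 44.3% (95% Wilson interval 44.283% to 44.318%), lay within the range of the lactate libraries (43.2%, 43.166% to 43.204%, to 44.6%, 44.595% to 44.629%), as a shift of whole libraries between gene-end and other peaks would give. Such a shift may be technical or an effect of lactate. Over peaks away from gene ends alone, NaCl 3 stood at 0.633 and NaCl 1 and NaCl 2 at 0.234 and 0.145. With 1 scaling for all peaks a shift of whole libraries moves these peaks too, so these positions cannot tell whether it covers them. That part stays open.

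Pyruvate changed transcripts, but no peak was called without a replicate term in the model, and 1 with it. Extra spread from NaCl 3 would predict calls without it; edgeR called 0 peaks there, while the count for lactate against NaCl rose to 11317. That fit had fewer libraries, and its peaks at an unadjusted p under 0.05 rose from 4060 to 4943. Extra spread from NaCl 3 is thus not excluded. The scaling of the libraries could hide peaks, but the 4 other scalings called 0. Changes of accessibility too small to be called one by one may still be present: the gene-end peaks of genes that rose and that fell differed in median log2 fold change by -0.0029 (permutation p = 0.4), which leaves it open. At the smallest change simulated, 6% of peaks were recovered against 60% of genes. A difference in how readily each assay calls small changes is thus not excluded. A biological separation of transcripts and accessibility was not tested.

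Of the myeloid and dendritic cell markers, 6 of 9 measured rose and 1 fell with Oxyrase against lactate; the list test passed (adjusted p = 0.0376) but not with an estimated correlation (0.11). Lyz2, among the most abundant transcripts of macrophages and monocytes, had 0 counts over the 3 Oxyrase libraries (up to 0.0332 CPM by the floor over the group) and 9 over all 12 libraries, and C1qa had 0 over the 12, which argues against macrophages or monocytes in the cultures; the CD8 T cells had been purified with magnetic beads. Dendritic cells would bring H2-Aa and H2-Eb1 along with H2-Ab1, but these together gained 0.04 ± 0.33 CPM (SE) while H2-Ab1 gained 8.30 ± 1.16 CPM, which argues against dendritic cells as the source of the rise in H2-Ab1. Itgax, another dendritic marker, went from 3, 3 and 1 counts to 26, 17 and 25, a gain of 0.70 ± 0.11 CPM. At so few counts the same 0.04 ± 0.33 CPM leaves dendritic cells open as its source. A lower share of CD8 T cells would raise the markers of other cells alike, but Ighm changed by -1.45 and Cd74 by 1.06. A change of these transcripts within the T cells may remain as a hypothesis; it was not tested.

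Transcripts moved by pyruvate were often moved by Oxyrase as well, although pyruvate against NaCl and Oxyrase against lactate share no library. Across genes, which are not independent replicates, r was 0.342 (0.004 in simulations with no effect); 924 genes rose in both, where independent lists would share 361.4, and 541 fell in both (218.5), while 216 went in opposite directions. A candidate explanation is a response that both treatments share, such as one to a changed redox balance, which was not measured. Among genes above the median of mean log2 CPM r was 0.299 (simulated -0.044), and across peaks it was 0.224 (simulated -0.001).

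For each comparison the 6 libraries make 10 splits, too few for a share under 0.05; 1 split, the real one, gave as many calls in each, except that all 10 did for pyruvate against NaCl in ATAC. With only the compared libraries in the model, the RNA counts of the real split and the highest other were 2365 and 0 for pyruvate and 994 and 1 for lactate against NaCl, 6980 and 0 for Oxyrase against lactate, 3612 and 0 for pyruvate against lactate, and 7144 and 0 for Oxyrase with lactate against NaCl. In ATAC they were 0 and 49, 3788 and 1184, 21888 and 24, 11819 and 0, and 29091 and 0 in the same order. The 49 came from pyruvate 1, pyruvate 3 and NaCl 3 against the rest, which points to a structure of the samples, and the 1184 from lactate 1, NaCl 1 and NaCl 2 against lactate 2, lactate 3 and NaCl 3.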
